A study of Mus musculus with 30 samples.

How the data were processed

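The data are total RNA sequencing of the abdominal aorta of wild-type C57BL/6 mice, with 30 libraries in 6 groups of 5. Per the labels, mice received saline (Control), angiotensin II by infusion at 500 ng/kg/min (AngII), or the same infusion together with 1 of 4 compounds for 28 days. The compounds were ethoxysanguinarine (AngII+ETH), baicalin (AngII+BAI) and gastrodin (AngII+GAS), each at 5 mg/kg/day, and the type 1 angiotensin receptor blocker valsartan (AngII+VAL) at 10.4 mg/kg/day. Angiotensin II is the peptide hormone that constricts arteries and raises blood pressure. Per the labels' protocols, ribosomal RNA was depleted and libraries were made with a NEBNext kit that does not mark strand. Values of antisense and overlapping genes, and of close paralogs, are therefore uncertain, and the use of strand in counting was not given in the sources used here.

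The authors deposited FPKM values (fragments per kilobase of transcript, scaled to library size) per transcript, for annotated mouse transcripts and for transcripts assembled from the reads. The unit was inferred from the values, since no header names it. Per the submitters' processing notes the genome build was mm10 and limma was used, with no version. The aligner, the assembler and the quantifier were not given in the sources used here. Each group had its own list of transcripts, and on testing the values a transcript was listed when its mean in the group itself or in AngII reached 0.5 FPKM. Control and AngII shared a list of 42860 transcripts. The lists of the compound groups held 42448 (AngII+ETH), 43742 (AngII+BAI), 42610 (AngII+GAS) and 42614 (AngII+VAL) transcripts. The union held 49085 transcripts, and 39267 were listed for all groups. Of the 33677 Ensembl transcripts, 33638 matched the GENCODE M21 annotation of GRCm38, which gave gene names and coordinates.

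The 27824 annotated transcripts listed for all groups were summed to 14379 genes. Sums over transcripts rest on how the authors' quantifier divided reads between isoforms, and transcripts outside the shared list do not enter them. Depth was read from the low values, which are whole multiples of the value of 1 read. Between 98.6% and 98.9% of the low values of a library came within 0.1 read of a whole number. The reads behind the FPKM values were 69.8 to 80.8 M (megareads) per library, of which 77.5% to 85.4% lay in annotated transcripts. A floor of 3 reads in a transcript of 2 kb corresponded to 0.0186 to 0.0215 FPKM. Floors of this kind cover counting error only.

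Genes with at least 1 FPKM in at least 5 of the 30 libraries were tested, which left 13223 genes. Log2(FPKM + 1) was fitted with limma 3.58.1 (lmFit, contrasts.fit and eBayes with trend and robust) in R 4.3.3. One mean per group was fitted over all 30 libraries, with 24 residual and 2.58 prior degrees of freedom. Tests were two-sided, with Benjamini-Hochberg adjustment over the genes of a comparison and a threshold of 0.05. Fold changes, on the log2(FPKM + 1) scale, are given with their standard error (SE) and understate the change of low genes. Tables and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Data were simulated for AngII against Control (13223 genes, 100 changed at each size). The model recovered 69% of log2 changes of 1 and 86% of 2, with 5 false calls. These values need not hold for more variable genes, such as Col1a1 (SE 0.49). Real libraries may differ too: regrouping AngII+BAI and AngII called up to 927 genes. Of unchanged simulated genes, 5.09% had an unadjusted p under 0.05.

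The main comparisons were AngII against Control and each compound group against AngII. The others set each compound group against Control, and the 3 plant compounds against valsartan. Gene lists for pathways and cell types of the vessel and its surroundings were fixed as 40 lists with 856 members together. Of these, 4 had fewer than 5 tested members, and 36 were tested with camera at a preset correlation of 0.01, adjusted over 180 tests (36 lists in 5 main comparisons). Camera asks whether a list's genes shift relative to all other genes. The lists were also tested with an estimated correlation, whose p, adjusted likewise, is given as the correlation p, with fry, and with an exact two-sided permutation test of the list score, the mean log2(FPKM + 1) of its members. The smallest p of that exact test is 0.0079, from 126 splits of 5 against 5.

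The design, the tests, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. Named genes are up to 12 per direction among genes past the threshold with ranges that do not overlap and a group mean of at least 5 FPKM. Where a direction had fewer than 5 such genes, the 3 genes with the smallest p were added. Another 12 genes of the renin-angiotensin system, contraction, matrix and endothelium were named in every main comparison. Up to 3 genes per direction were named in the other comparisons, and members of called lists were named by smallest p. Members were named only for the 6 called lists with the smallest camera p, 2 each, a choice made after seeing the data. Some genes named by the rule are not reported here.

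Alternatives planned were pseudocounts of 0.1 and 5, no filter and a filter at 5 FPKM, quantile normalization and TMM factors, limma without trend and robust, a model of the 2 groups compared alone, array quality weights, and leaving out each library in turn. Alternatives added after seeing the data were voom on the recovered reads, unlisted transcripts set to 0, transcripts in place of genes, terms for kidney transcript level or for the neuron and skeletal muscle scores (which removes these 2 lists by construction), leaving out baicalin libraries 3 and 5 or 1, 3 and 5, and quantile normalization for the reversal of angiotensin II changes. The labels gave no batch, litter or pairing, and replicate numbers only name libraries. They state samples per group and not separate animals, so p-values measure the spread between these samples, which may be technical in part.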

Results

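The 30 libraries came from the abdominal aorta, 5 per group. Mice received saline (Control), angiotensin II (AngII), or angiotensin II with ethoxysanguinarine (AngII+ETH), baicalin (AngII+BAI), gastrodin (AngII+GAS) or valsartan (AngII+VAL). Ethoxysanguinarine is a plant alkaloid, baicalin a flavonoid glucuronide and gastrodin a phenolic glucoside. The series title describes compounds that lower the blood pressure raised by angiotensin II. Means are given ± SD over 5 libraries. Mitochondrially encoded genes took 20.2% ± 1.39 of the FPKM in Control, 14.97% ± 4.27 in AngII and 14.8% ± 4.25 to 20.7% ± 4.87 in the compound groups.

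AngII was compared with Control to ask what the infusion changed. As lists, genes of the extracellular matrix, fibroblasts, neurons and Schwann cells were called higher in AngII, which did not hold with an estimated correlation (adjusted p = 0.374 to 0.699). Genes of oxidative phosphorylation, fatty acid oxidation, the mitochondrial genome, brown adipocytes and skeletal muscle were called lower (adjusted p = 0.299 to 0.544 with an estimated correlation). The mean log2 level of 40 matrix genes was 5.49 ± 0.65 in AngII and 4.70 ± 0.21 in Control, and that of 40 oxidative phosphorylation genes 7.14 ± 0.31 against 7.58 ± 0.24. None of 13223 single genes passed limma's threshold (0 higher, 0 lower) and voom called 0, array weights 64 and a fit without AngII+BAI 3 and 5 18, while 1480 genes had an unadjusted p under 0.05 (median of other splits of these libraries 405). The count was 41 without AngII 2, 5 without AngII 3, 1 without AngII 4 and 1 without Control 5. The median log2 fold change of all genes was 0.11, against −0.023 after quantile normalization, a shift to which fold changes are relative.

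Masp1 and Lrrn2 were among the higher genes with the smallest p. Masp1 (ENSMUSG00000022887, GRCm38 chromosome 16, 23449417 to 23520815, minus strand), a protease of the lectin pathway of complement, was at 2.11 ± 0.578 against 0.735 ± 0.12 FPKM (log2 fold change 0.83, SE 0.15, adjusted p = 0.053). Lrrn2, which encodes a leucine-rich repeat membrane protein, was at 3.01 ± 1.13 against 1.08 ± 0.145 FPKM (0.90, SE 0.17, adjusted p = 0.053). On the lower side stood Hspd1, the mitochondrial chaperonin (49.6 ± 5.37 against 104 ± 19.3 FPKM; −1.03, SE 0.27, adjusted p = 0.16), Tmem110 (27.6 ± 6.83 against 43.1 ± 5.5 FPKM; −0.65, SE 0.17, adjusted p = 0.16) and Klhl23 (0.389 ± 0.56 against 3.46 ± 1.08 FPKM; −1.73, SE 0.48, adjusted p = 0.19).

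Among the genes named in every main comparison, the fibrillar collagen genes Col1a1 (ENSMUSG00000001506, chromosome 11, 94936224 to 94953042, plus strand) and Col3a1 had log2 fold changes of 1.59 (SE 0.49, adjusted p = 0.23) and 1.43 (SE 0.51, adjusted p = 0.29). Col1a1 was at 666 ± 519 FPKM in AngII and 185 ± 37.2 in Control. Fibronectin, Fn1, was at 407 ± 82.5 against 164 ± 57.1 FPKM (1.36, SE 0.53, adjusted p = 0.32). Agtr1a, the main vascular receptor of angiotensin II, had 0.83 (SE 0.36, adjusted p = 0.37; 0.121 with the neuron and muscle scores as terms), with 9.16, 7.26 and 16 FPKM in AngII 1, 4 and 5, where neuron genes were high, and 4.13 and 2.82 in AngII 2 and 3. Ace, which makes angiotensin II from angiotensin I, had 0.61 (SE 0.29, adjusted p = 0.42). The contractile genes Acta2, Myh11, Mylk and Myl9 had log2 fold changes of −0.04 (SE 0.39), 0 (SE 0.38), 0.13 (SE 0.29) and 0.21 (SE 0.40), with adjusted p of 0.89 to 1. Acta2, smooth muscle actin, was at 3880 ± 517 FPKM in AngII and 4060 ± 1010 in Control. Nos3, endothelial nitric oxide synthase, had 0.33 (SE 0.33, adjusted p = 0.74), Pparg −0.08 (SE 0.28, adjusted p = 0.94), and the monocyte chemokine gene Ccl2 0.37 (SE 0.72, adjusted p = 0.89). The list of 13 genes of the renin-angiotensin-aldosterone system did not pass (camera, adjusted p = 0.0573). In it 6 higher and 1 lower members passed adjusted over the list alone, 0 over all genes.

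Camera with a preset correlation called 13 of 36 lists for AngII against Control, 5 up and 8 down, and in every main comparison 0 with an estimated correlation (correlation p). By the exact test of list scores 0 lists passed after adjustment in any main comparison (lowest adjusted p = 0.338). Fry, which asks whether the genes of a list move one way, called Schwann cells for AngII against Control (adjusted p = 0.047) and gastrodin (0.027), calcium signalling for baicalin (0.02), skeletal muscle for valsartan (0.026) and 0 lists for ethoxysanguinarine. No member of any of the 13 passed over all genes tested. Nuclear-encoded oxidative phosphorylation had 38 of 40 members lower (adjusted p = 4.9e-17, correlation p = 0.544), with Sdhc, of complex II, at −0.52 (SE 0.21, adjusted p = 0.34). Fatty acid oxidation had 23 of 27 members lower (mean difference −0.57; adjusted p = 4.6e-12, correlation p = 0.338). Its members Pdk4, a kinase that shuts off pyruvate dehydrogenase, and Ucp3 were at −1.43 (SE 0.42, adjusted p = 0.21) and −0.84 (SE 0.31, adjusted p = 0.3). Brown and perivascular adipocyte thermogenesis had 18 of 19 members lower (mean difference −0.59; adjusted p = 2.4e-08, correlation p = 0.397), among them Plin5, a lipid droplet protein, at −0.97 (SE 0.38, adjusted p = 0.33), and Fabp3 at −1.42 (SE 0.61, adjusted p = 0.37). The mitochondrially encoded genes had 8 of 9 members lower (−0.81; adjusted p = 1.6e-05, correlation p = 0.299; exact permutation p = 0.0079, adjusted p = 0.338), a call that quantile normalization ended. The matrix list had 37 of 40 members higher (0.78; adjusted p = 1.4e-05, correlation p = 0.67), and the fibroblast list 16 of 17 (0.56; adjusted p = 0.0038, correlation p = 0.699). With the neuron and muscle scores as terms the oxidative phosphorylation, fibroblast and Schwann cell calls were lost (adjusted p = 0.054, 0.176 and 0.0846), with the cholesterol, white adipocyte and mesothelial calls. Adjusted over the list alone, 2 fibroblast genes passed and 0 of the matrix, oxidative phosphorylation, fatty acid oxidation, brown adipocyte and mitochondrial lists.

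Markers of other tissues were high in part of the AngII or Control libraries. All 23 neuron and sympathetic ganglion genes were higher (mean difference 2.21; adjusted p = 2.3e-10, correlation p = 0.602), and 18 passed when adjusted over the list alone. Their score was 5.15 in AngII 1, 3.54 in AngII 4 and 5.45 in AngII 5, against 0.527 in AngII 2, 0.737 in AngII 3 and 0.475 to 2.24 in Control. Hand2, a transcription factor of sympathetic neurons, was at 10.7 ± 11 FPKM against 0.555 ± 0.568 (2.28, SE 0.68, adjusted p = 0.22), and Gap43, a growth cone protein, at 21.6 ± 26.2 against 0.954 ± 1.14 (2.48, SE 0.90, adjusted p = 0.29). The Schwann cell list had 13 of 13 members higher (0.95; adjusted p = 7.4e-06, correlation p = 0.374), and 8 passed adjusted over the list alone. The myelin genes Mal and Prx in it were at 1.24 (SE 0.38, adjusted p = 0.22) and 0.86 (SE 0.27, adjusted p = 0.23). Skeletal muscle genes had 17 of 17 members lower (−1.55; adjusted p = 3.2e-09, correlation p = 0.515; 0 passed adjusted over the list alone). The muscle score was 5.46 in Control 1 and 6.65 in Control 2, against 1.40 to 2.19 in the other Control libraries and 1.25 to 2.56 in AngII. Casq1 and Myoz1, of the sarcoplasmic reticulum and the Z-disc, were at −1.14 (SE 0.47, adjusted p = 0.35) and −1.98 (SE 0.86, adjusted p = 0.38).

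The other 4 calls depended on single libraries. Erythrocyte and platelet genes had 9 of 10 members lower (−0.47; adjusted p = 0.00055, correlation p = 0.602), and the call was lost without AngII 2 (adjusted p = 0.0817). Cholesterol synthesis genes had 17 of 21 members higher (0.33; adjusted p = 0.0117, correlation p = 0.699), with 4 passing adjusted over the list alone. That call was lost without Control 3, AngII 1 or AngII 5 (adjusted p = 0.0668, 0.0841 and 0.169). White adipocyte genes had 17 of 26 members lower (−0.017; adjusted p = 0.0121, correlation p = 0.699), lost without Control 4 or AngII 3 (adjusted p = 0.0932 and 0.0851). Mesothelial genes had 5 of 6 members lower (−0.39; adjusted p = 0.0336, correlation p = 0.699), lost without Control 2, 3 or 4 or AngII 1, 3 or 5 (adjusted p = 0.0729 to 0.253). Of the erythrocyte, adipocyte and mesothelial genes 0 passed adjusted over the list alone. Quantile normalization also ended the white adipocyte and mesothelial calls, and voom and the kidney level term the mesothelial call. Over all settings the adjusted p of the 13 lists was 2.2e-19 to 0.875.

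**Figure D1:**
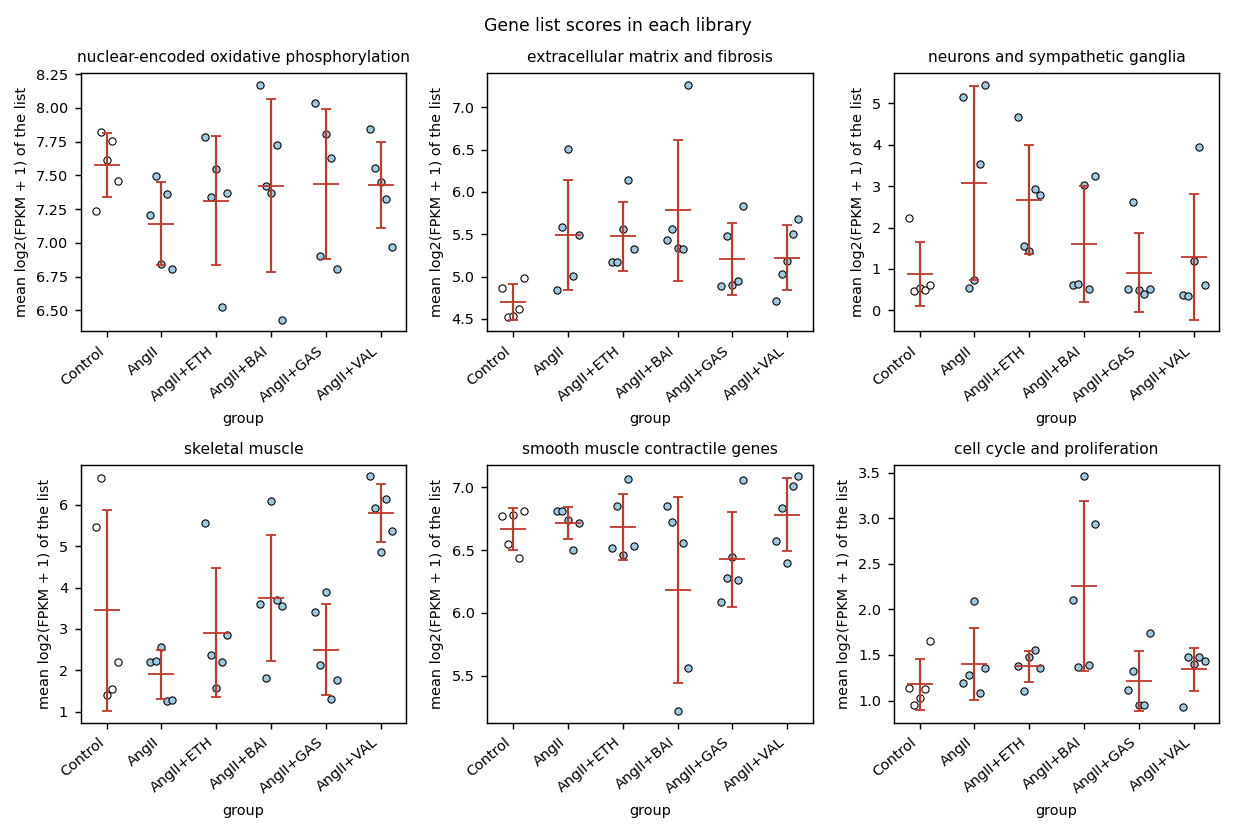
Mean log2(FPKM + 1) of the members of 6 gene lists in each of the 30 libraries, by group; points are libraries (open for Control) and red bars the mean ± SD of 5 libraries. The skeletal muscle score was 5.80 ± 0.71 in AngII+VAL and 1.90 ± 0.60 in AngII, and the neuron score of single AngII libraries ran from 0.527 to 5.45.

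Ethoxysanguinarine was compared with AngII to ask what it changed. As lists, genes of oxidative phosphorylation, fatty acid oxidation, the mitochondrial genome, brown adipocytes, skeletal muscle and the circadian clock were called higher, although 8 of 19 clock genes were lower, and Schwann cell genes lower. None of these calls held with an estimated correlation (adjusted p = 0.0839 to 0.699), and the brown adipocyte and Schwann cell calls were lost without AngII 5. The oxidative phosphorylation score was 7.31 ± 0.48 against 7.14 ± 0.31, a mean difference of 0.17, and the clock score 2.73 ± 0.16 against 2.52 ± 0.10, a mean difference of 0.21. No single gene passed limma's threshold (0 higher, 0 lower) and voom called 0. At an unadjusted p under 0.05 there were 451 genes (median of other splits of these libraries 402), and 1 gene passed without AngII+ETH 5.

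The higher genes with the smallest p were Dyrk1b, a kinase (9.75 ± 2.3 against 4.55 ± 2.93 FPKM; log2 fold change 1.06, SE 0.28), Nr1d1, a repressor in the circadian clock (73.1 ± 30.7 against 20.3 ± 9.03; 1.73, SE 0.47), and Sparc, a matrix-binding glycoprotein (1560 ± 348 against 438 ± 758; 3.22, SE 0.88). Sparc was at 57.4 to 1790 FPKM within AngII. On the lower side were Pex5l (0.697 ± 0.808 against 3.44 ± 1.77 FPKM; −1.41, SE 0.31) and Masp1 (1.07 ± 0.436 against 2.11 ± 0.578; −0.59, SE 0.15). Over the shared transcripts Agap2 was at 0 in all 5 AngII+ETH libraries and in AngII 3, and at 1.04 to 1.47 FPKM in the other 4 AngII libraries. With unlisted transcripts set to 0 its log2 fold change turned from −0.94 to 0.27. Adjusted p was 0.81 for Pex5l and 0.99 for the others. Col1a1 was at 454 ± 164 FPKM with compound and 666 ± 519 without (−0.35, SE 0.49), and Col3a1 had −0.37 (SE 0.51). Fn1 had 0.25 (SE 0.53), Agtr1a −0.34 (SE 0.36), Ace −0.28 (SE 0.29), Nos3 −0.20 (SE 0.33), Pparg −0.17 (SE 0.28) and Ccl2 0.03 (SE 0.72). Acta2, Myh11, Mylk and Myl9 had 0.02 (SE 0.39), −0.06 (SE 0.38), −0.03 (SE 0.29) and −0.22 (SE 0.40). The adjusted p of these 12 genes was 0.99 or 1.

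Camera called 8 lists for AngII+ETH against AngII, 7 up and 1 down; no member passed over all genes. Oxidative phosphorylation had 36 of 40 members higher (adjusted p = 6.3e-09, correlation p = 0.699), with the ATP synthase subunit Atp5d at 0.52 (SE 0.29) and Atp5g1 at −1.10 (SE 0.60). Skeletal muscle had 16 of 17 higher (mean difference 1.01; adjusted p = 2.1e-07, correlation p = 0.581). Its score was 5.57 in AngII+ETH 1 and at most 2.84 in the others, and Acta1, skeletal actin, was at 151 ± 269 against 12 ± 12.9 FPKM (2.49, SE 1.51) and Mylpf at 1.98 (SE 1.23). Mitochondrially encoded genes had 9 of 9 higher (0.64; adjusted p = 8.8e-05, correlation p = 0.338), a call ended by quantile normalization, with mt-Nd6 at 0.39 (SE 0.31; 0.156 without AngII 5, 0.649 without AngII+ETH 4) and mt-Co2 at 0.33 (SE 0.27; 0.216 and 0.576). Fatty acid oxidation had 21 of 27 higher (0.18; adjusted p = 0.000237, correlation p = 0.668), with Ppard, the nuclear receptor of this pathway, at −0.26 (SE 0.13). The clock list had 11 members higher and 8 lower (adjusted p = 0.00226, correlation p = 0.0839), and in it 1 gene, Nr1d1, passed when adjusted over the list alone, while Nfil3, a clock output repressor, was at −0.96 (SE 0.34). Brown adipocyte genes had 14 of 19 higher (0.30; adjusted p = 5.4e-05, correlation p = 0.608), with Ucp1, the thermogenic uncoupling protein, at 1860 ± 828 against 1140 ± 606 FPKM (0.76, SE 0.55; 0.309 and 1.199 likewise) and Plin5 at 0.66 (SE 0.38), and the call was lost without AngII 5 (adjusted p = 0.253). Schwann cell genes had 11 of 13 lower (−0.50; adjusted p = 0.0086, correlation p = 0.659), lost without AngII 5 or AngII+ETH 3 (adjusted p = 0.39 and 0.0707). Glucocorticoid response genes had 8 of 14 higher (0.092; adjusted p = 0.0364, correlation p = 0.541), lost without AngII 1, 2 or 5 or AngII+ETH 2, 3 or 5 (adjusted p = 0.0583 to 0.252). With the neuron and muscle scores as terms the Schwann cell call was lost (adjusted p = 0.0588), under quantile normalization the glucocorticoid call, and by voom the Schwann cell and glucocorticoid calls (adjusted p = 0.0591 and 0.0691). Besides the clock list, 0 members passed adjusted over the list alone. The adjusted p of the members named here was 0.99, and that of the 8 lists over all settings was 4.0e-19 to 0.699.

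Baicalin was compared likewise. By limma 44 genes passed the threshold against AngII, of which 42 fell and 2 rose, and 0 passed with array weights or in a model of the 2 groups alone. Genes that fell included Gucy1a1, a subunit of soluble guanylate cyclase, the receptor of nitric oxide, at 18.5 ± 5.78 against 36.8 ± 9.81 FPKM, and Kit, the stem cell factor receptor, at 2.8 ± 0.93 against 7.16 ± 3.16 FPKM. Slc39a1, a zinc importer, rose from 26.4 ± 7.39 to 57.1 ± 13.9 FPKM. As lists, cell cycle, ribosomal protein, skeletal muscle and immune (macrophage, inflammatory, MHC class II and T cell) genes were called higher, and contractile, calcium signalling, neuron and Schwann cell genes lower. None of these calls held with an estimated correlation (adjusted p = 0.299 to 0.758), and the contractile and immune calls were lost without AngII+BAI 3 and 5 (adjusted p = 0.283 for contractile and 0.887 for macrophage genes). The contractile score was 5.22 in AngII+BAI 3 and 5.56 in AngII+BAI 5, against 6.55 to 6.85 in the others.

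Quantile normalization gave 7 genes higher and 23 lower, TMM factors 10 and 56, and voom 1 and 22, of which 19 were among the 44. With a term for kidney level 64 passed, 32 of them among the 44. The count was 9 without AngII 1, 106 without AngII 2, 82 without AngII 3, 0 without AngII 5, 184 without AngII+BAI 2, 0 without AngII+BAI 3 and 76 without AngII+BAI 5. Without AngII+BAI 3 and 5 together it was 102, and 15 of these were among the 44. At an unadjusted p under 0.05 there were 1936 genes. Nrbp2 (ENSMUSG00000075590, chromosome 15, 76085518 to 76091627, minus strand), a pseudokinase gene, had the smallest adjusted p, with 16.1 ± 2.82 against 25.5 ± 3.07 FPKM (−0.64, SE 0.12, adjusted p = 0.022). Fam174b (ENSMUSG00000078670, chromosome 7, 73740302 to 73776919, plus strand) fell from 10.5 ± 3.99 to 4.25 ± 0.762 FPKM (−1.08, SE 0.21, adjusted p = 0.029). The glutathione transferase genes Gsta3 (ENSMUSG00000025934, chromosome 1, 21240589 to 21265661, plus strand) and Gstm1 fell by 2.03 (SE 0.42, adjusted p = 0.029) and 0.88 (SE 0.19, adjusted p = 0.037) on the log2 scale, and have close paralogs. Gucy1a1 (ENSMUSG00000033910, chromosome 3, 82092427 to 82145789, minus strand) fell by 0.99 (SE 0.22, adjusted p = 0.047) and Kit (ENSMUSG00000005672, chromosome 5, 75574916 to 75656722, plus strand) by 1.07 (SE 0.23, adjusted p = 0.037). Slc39a1 (ENSMUSG00000052310, chromosome 3, 90248172 to 90253612, plus strand) rose by 1.09 (SE 0.23, adjusted p = 0.031).

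Other genes lower with baicalin were Tnrc18 (−2.41, SE 0.50, adjusted p = 0.029; 3.04 ± 4.01 against 13 ± 2.58 FPKM), Dpep1, a membrane dipeptidase (−1.5, SE 0.33, adjusted p = 0.037; 41.5 ± 23.8 against 99.8 ± 19 FPKM), and Flt3l, the ligand of a receptor on dendritic cell precursors (−1.10, SE 0.21, adjusted p = 0.029). Atp1b2, a sodium pump subunit (10.4 ± 2.48 against 21.5 ± 6.48 FPKM), and Ndrg1 (43.3 ± 5.95 against 87.9 ± 30.6 FPKM) also fell, each with adjusted p = 0.029. Hdc, which encodes the enzyme that makes histamine, rose by 0.90 (SE 0.20, adjusted p = 0.042), and Cib1 was at 0.74 (SE 0.17, adjusted p = 0.051). Of the genes named in every comparison none passed: Myh11 was at 333 ± 212 against 528 ± 56.8 FPKM (−1.02, SE 0.38, adjusted p = 0.21), Myl9 at −1.06 (SE 0.40, adjusted p = 0.22), Mylk at −0.64 (SE 0.29, adjusted p = 0.31) and Acta2 at −0.43 (SE 0.39, adjusted p = 0.61). Ace was at 66.9 ± 29 against 115 ± 20.1 FPKM (−0.91, SE 0.29, adjusted p = 0.14), Agtr1a at −0.71 (SE 0.36, adjusted p = 0.36) and Fn1 at −1.12 (SE 0.53, adjusted p = 0.33). Col1a1 was at 864 ± 1180 FPKM (−0.09, SE 0.49, adjusted p = 0.94), with 2980 FPKM in AngII+BAI 5, and Col3a1 at 0.33 (SE 0.51, adjusted p = 0.79). Nos3 had 0.37 (SE 0.33, adjusted p = 0.6), Pparg −0.29 (SE 0.28, adjusted p = 0.64) and Ccl2 1.38 (SE 0.72, adjusted p = 0.37).

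**Figure D2:**
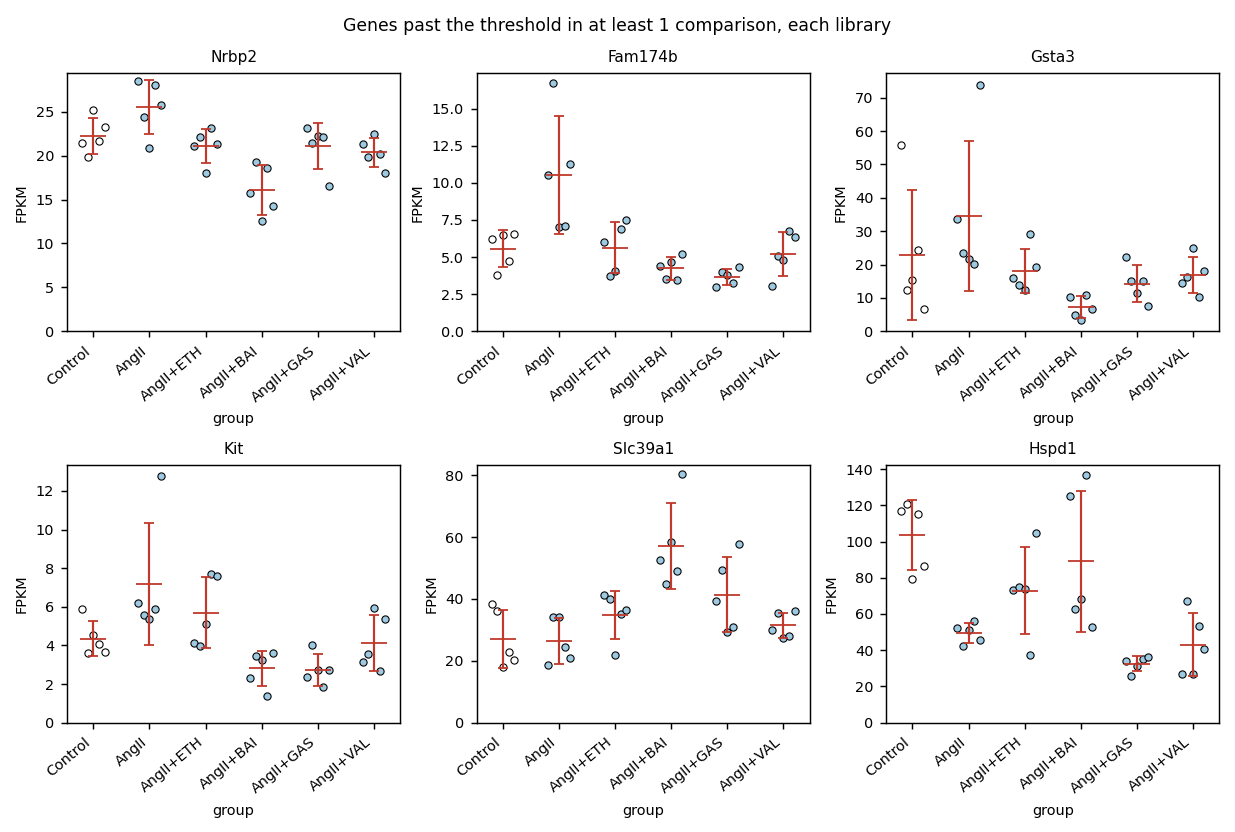
FPKM of Nrbp2, Fam174b, Gsta3, Kit, Slc39a1 and Hspd1 in each library by group; points are libraries and bars the mean ± SD of 5 libraries. Fam174b was at 10.5 ± 3.99 FPKM in AngII and 4.25 ± 0.762 in AngII+BAI.

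Camera called 18 lists for AngII+BAI against AngII, 11 up and 7 down. The 21 cell cycle genes were all higher (score 2.25 ± 0.93 against 1.40 ± 0.40, mean difference 0.85; adjusted p = 1.6e-12, correlation p = 0.397), and 14 passed adjusted over the list alone, 0 over all genes. Rrm2, of nucleotide reduction, and cyclin A, Ccna2, had 1.36 (SE 0.39, adjusted p = 0.12) and 1.36 (SE 0.41, adjusted p = 0.14). The score was 3.46 in AngII+BAI 3 and 2.94 in AngII+BAI 5, against 1.37 to 2.11 in the others. Ribosomal protein genes had 33 of 34 higher (0.35; adjusted p = 5.7e-09, correlation p = 0.659), with Rpl11 at 0.50 (SE 0.16, adjusted p = 0.16) and Rps2 at 0.49 (SE 0.20, adjusted p = 0.26), but 0.388 and 0.282 without AngII+BAI 1, which had the highest level of both. Contractile genes had 29 of 30 lower (6.18 ± 0.74 against 6.72 ± 0.13, −0.53; adjusted p = 2.0e-05, correlation p = 0.67), and calcium signalling genes 23 of 27 (−0.36; adjusted p = 0.00044, correlation p = 0.299), 5 of which passed adjusted over the list alone. Endoplasmic reticulum stress genes had 16 of 22 higher (0.30; adjusted p = 0.00044, correlation p = 0.581), 3 of them adjusted over the list alone. Skeletal muscle genes had 16 of 17 higher (1.85; adjusted p = 1.0e-05, correlation p = 0.659), with Mylpf at 3.38 (SE 1.23, adjusted p = 0.2) and Acta1 at 3.90 (SE 1.51, adjusted p = 0.23), and a score of 6.09 in AngII+BAI 3. The 23 neuron genes were all lower (−1.48; adjusted p = 2.2e-05, correlation p = 0.713), with Hand2 at −1.47 (SE 0.68, adjusted p = 0.32). Schwann cell genes had 12 of 13 lower (−0.89; adjusted p = 2.2e-05, correlation p = 0.389), 6 of them adjusted over the list alone, with Prx at −1.12 (SE 0.27, adjusted p = 0.057) and Erbb3 at −0.95 (SE 0.25, adjusted p = 0.091). In the ribosomal, contractile, muscle and neuron lists 0 members passed adjusted over the list alone.

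Another 10 list calls for baicalin were lost without single libraries. Macrophage (mean difference 0.49), inflammatory cytokine (0.50), MHC class II (0.74) and T cell (0.54) genes were higher, with adjusted p = 0.0028, 0.0058, 0.0053 and 0.019 (correlation p = 0.758, 0.745, 0.699 and 0.733). The macrophage score was 5.99 in AngII+BAI 3 and 5.33 in AngII+BAI 5, against 3.96 to 4.32 in the others. The macrophage and inflammatory calls were lost without AngII+BAI 3, and the inflammatory, MHC class II and T cell calls without AngII+BAI 5 (adjusted p = 0.0845 to 0.499). Oxidative phosphorylation genes (0.28; adjusted p = 0.00025, correlation p = 0.867) lost their call without AngII+BAI 1 (adjusted p = 0.137) and under quantile normalization (adjusted p = 0.216). Glucocorticoid response genes (0.48; adjusted p = 0.0091, correlation p = 0.389) lost it without AngII+BAI 2 (adjusted p = 0.188). Immediate early genes (0.23; adjusted p = 0.0234, correlation p = 0.699) lost it without AngII 5, AngII+BAI 1 or AngII+BAI 2 (adjusted p = 0.227, 0.0638 and 0.0744). On the lower side, cholesterol synthesis genes (−0.30; adjusted p = 0.0038, correlation p = 0.669) lost it without AngII 5 (adjusted p = 0.0653) and white adipocyte genes (−0.42; adjusted p = 0.0117, correlation p = 0.699) without AngII+BAI 5 (adjusted p = 0.328). Endothelial genes (−0.29; adjusted p = 0.014, correlation p = 0.67) lost it without AngII 4 or AngII+BAI 1 (adjusted p = 0.0754 and 0.346). Adjusted over the list alone, 1 gene passed in each of the immediate early, cholesterol and endothelial lists and 0 in the others. Without both AngII+BAI 3 and 5 the white adipocyte and cholesterol calls were lost too. Array weights ended the contractile, immune, white adipocyte, endothelial and immediate early calls, quantile normalization the last and the glucocorticoid call, and voom the T cell call (adjusted p = 0.0511). A term for kidney transcript level ended the macrophage, inflammatory, MHC class II, T cell and white adipocyte calls (adjusted p = 0.0527, 0.129, 0.0903, 0.524 and 0.319). With the neuron and muscle scores as terms the endothelial, cholesterol, immediate early and oxidative phosphorylation calls were lost, and the direction of the last turned. The list of vasoactive receptors and nitric oxide signalling did not pass (adjusted p = 0.0743), although 6 of its members were lower adjusted over the list alone and 1, Gucy1a1, over all genes. The adjusted p of the 18 lists over all settings was 5.9e-16 to 0.984.

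Gastrodin was also set against AngII. Fam174b and Lrrn2 fell below their AngII level. Fam174b was at 3.65 ± 0.535 FPKM against 10.5 ± 3.99 (−1.25, SE 0.21, adjusted p = 0.037) and Lrrn2 (ENSMUSG00000026443, chromosome 1, 132880273 to 132940005, plus strand) at 1.03 ± 0.331 against 3.01 ± 1.13 (−0.95, SE 0.17, adjusted p = 0.037). As lists, oxidative phosphorylation, fatty acid oxidation and brown adipocyte genes were called higher, and neuron, Schwann cell and cholesterol synthesis genes lower, none of which held with an estimated correlation (adjusted p = 0.374 to 0.67). The oxidative phosphorylation score was 7.44 ± 0.55 against 7.14 ± 0.31 and the cholesterol synthesis score 3.17 ± 0.20 against 3.64 ± 0.43. The median log2 fold change of all genes was −0.17, against 0.013 after quantile normalization. By limma 2 genes passed, 0 higher and 2 lower, with 1807 at an unadjusted p under 0.05, and voom, quantile normalization and a model of the 2 groups alone called 0, while array weights called 232. The count was 61 without AngII 2, 5 without AngII 3, 1 without AngII+GAS 1, and 0 without AngII 1, AngII 5 or AngII+GAS 2, 3 or 4.

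The next smallest p among the lower genes was that of Masp1 (0.816 ± 0.418 against 2.11 ± 0.578 FPKM; −0.79, SE 0.15, adjusted p = 0.077). Of the higher genes, Trib1, a pseudokinase (14 ± 3.62 against 6.37 ± 1.59 FPKM; 1.02, SE 0.23), Dag1, dystroglycan (90.9 ± 29.8 against 32.2 ± 3.99; 1.39, SE 0.34), and Nr1d1 (81.7 ± 34.3 against 20.3 ± 9.03; 1.93, SE 0.47) each had adjusted p = 0.17. Col1a1 was at 331 ± 150 against 666 ± 519 FPKM (−0.85, SE 0.49, adjusted p = 0.43), Col3a1 at 339 ± 155 against 801 ± 758 (−0.95, SE 0.51, adjusted p = 0.41) and Fn1 at 241 ± 220 against 407 ± 82.5 (−1.07, SE 0.53, adjusted p = 0.37). Agtr1a had −0.69 (SE 0.36, adjusted p = 0.39) and Ace −0.28 (SE 0.29, adjusted p = 0.66). Acta2, Myh11, Mylk and Myl9 had −0.21 (SE 0.39), −0.20 (SE 0.38), −0.06 (SE 0.29) and −0.68 (SE 0.40), with adjusted p of 0.44 to 0.94. Nos3 had −0.07 (SE 0.33, adjusted p = 0.94), Pparg 0.15 (SE 0.28, adjusted p = 0.82) and Ccl2 −0.42 (SE 0.72, adjusted p = 0.8).

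Camera called 12 lists for AngII+GAS against AngII, 8 up and 4 down; no member passed over all genes. Oxidative phosphorylation had 37 of 40 members higher (mean difference 0.29; adjusted p = 4.8e-14, correlation p = 0.594), with Sdhc at 0.37 (SE 0.21, adjusted p = 0.42) and Atp5d at 0.52 (SE 0.29, adjusted p = 0.42). Fatty acid oxidation had 21 of 27 higher (0.41; adjusted p = 1.8e-10, correlation p = 0.374), with Acot2, an acyl-CoA thioesterase, at 0.77 (SE 0.30, adjusted p = 0.26). Brown adipocyte genes had 17 of 19 higher (0.58; adjusted p = 4.6e-10, correlation p = 0.374), with Plin5 at 38.7 ± 19.3 against 16.8 ± 6.36 FPKM (1.08, SE 0.38, adjusted p = 0.24) and the fatty acid transporter gene Slc27a2 at 1.21 (SE 0.45, adjusted p = 0.25). Mitochondrially encoded genes had 7 of 9 higher (0.43; adjusted p = 6.2e-05, correlation p = 0.338), with mt-Nd6 at 0.73 (SE 0.31, adjusted p = 0.29), but under quantile normalization the list's direction turned and the call was lost. The 23 neuron genes were all lower (score 0.91 ± 0.96 against 3.08 ± 2.35; adjusted p = 9.3e-08, correlation p = 0.67), 18 of them adjusted over the list alone, with a score of 2.61 in AngII+GAS 2. Chga, of secretory granules, was at 0.397 ± 0.717 against 11.5 ± 14.5 FPKM (−2.08, SE 0.77, adjusted p = 0.25) and Hand2 at −2.12 (SE 0.68, adjusted p = 0.21). Schwann cell genes had 11 of 13 lower (−1.06; adjusted p = 1.4e-05, correlation p = 0.389), 9 of them adjusted over the list alone, with Sox10 at 0.226 ± 0.505 against 6 ± 6.03 FPKM (−2.06, SE 0.53, adjusted p = 0.17). Skeletal muscle genes had 14 of 17 higher (0.60; adjusted p = 0.00031, correlation p = 0.699), a call ended by quantile normalization (adjusted p = 0.0917). Cholesterol synthesis genes had 20 of 21 lower (−0.48; adjusted p = 0.0012, correlation p = 0.615), and 5 passed adjusted over the list alone.

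The other 4 calls were lost without single libraries. All 34 ribosomal protein genes were lower (−0.29; adjusted p = 0.0234, correlation p = 0.904), a call lost without AngII 3, AngII 5, AngII+GAS 2 or AngII+GAS 4 (adjusted p = 0.121 to 0.154). Mesothelial genes were higher (0.29; adjusted p = 0.0308, correlation p = 0.699), lost without AngII 1, 3 or 5 or AngII+GAS 4 (adjusted p = 0.0872 to 0.227). White adipocyte genes were called up with a mean difference of −0.087 and a median of 0.047 (adjusted p = 0.0307, correlation p = 0.745), and quantile normalization turned the direction. That call was lost without AngII 3 or AngII+GAS 1, 3 or 4 (adjusted p = 0.129 to 0.262). Immediate early genes were called up with a mean of −0.031 and a median of 0.006 (adjusted p = 0.0315, correlation p = 0.713), lost without AngII 1, 2 or 5 or AngII+GAS 1, 2 or 5 (adjusted p = 0.0716 to 0.313). Quantile normalization and array weights also ended the mesothelial and immediate early calls, voom the immediate early call, and leaving out AngII+BAI 3 and 5 the ribosomal call. With the neuron and muscle scores as terms the cholesterol, mesothelial, white adipocyte and immediate early calls were lost. In these 4 lists, and in the energy, adipocyte and muscle lists, 0 members passed adjusted over the list alone. The adjusted p of the 12 lists over all settings was 1.5e-21 to 0.905.

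Valsartan was compared with AngII as the drug reference. The skeletal muscle score was higher in every AngII+VAL library than in any AngII library (4.86 to 6.69 against 1.25 to 2.56). It was also 5.46 to 6.65 in Control 1 and 2, AngII+ETH 1 and AngII+BAI 3, without valsartan. As lists, oxidative phosphorylation, erythrocyte, fatty acid oxidation, brown adipocyte and B cell genes were also called higher, and neuron, Schwann cell and fibroblast genes lower. None of these calls held with an estimated correlation (adjusted p = 0.0775 for muscle and 0.374 to 0.713 for the others), the fibroblast call was lost without AngII 3, and with a term for kidney transcript level the B cell direction turned and the call was lost. The fibroblast score was 5.58 ± 0.24 against 6.08 ± 0.44. No single gene passed limma's threshold (0 higher, 0 lower) and voom called 0, with 1429 genes at an unadjusted p under 0.05. The count was 19 in a model of the 2 groups alone, 18 with unlisted transcripts set to 0 and 1 without AngII 5. The median log2 fold change of all genes was −0.12, against 0.001 after quantile normalization.

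The genes with the smallest p, each with adjusted p = 0.12, were Dyrk1b (12.2 ± 1.64 against 4.55 ± 2.93 FPKM; 1.37, SE 0.28), Cacna1s, the skeletal muscle calcium channel (ENSMUSG00000026407, chromosome 1, 136052750 to 136119822, plus strand; 9.15 ± 5.79 against 0.00834 ± 0.0114), and Myoz1 (25.4 ± 16 against 0.428 ± 0.514; 4.06, SE 0.86). Lower were Trmt13, a transfer RNA methyltransferase gene (0.665 ± 0.261 against 1.69 ± 0.444 FPKM; −0.69, SE 0.15), Bbs9, of primary cilia (1.81 ± 1.02 against 4.38 ± 0.745; −1.01, SE 0.22), and Nrn1, neuritin (2.33 ± 1.16 against 10.9 ± 9.08; −1.60, SE 0.35). Col1a1 was at 303 ± 118 against 666 ± 519 FPKM (−0.95, SE 0.49, adjusted p = 0.49) and Col3a1 at 358 ± 142 against 801 ± 758 (−0.86, SE 0.51, adjusted p = 0.56). Fn1 had −0.27 (SE 0.53, adjusted p = 0.88), Agtr1a −0.68 (SE 0.36, adjusted p = 0.5) and Ace −0.35 (SE 0.29, adjusted p = 0.67). Acta2, Myh11, Mylk and Myl9 had 0.19 (SE 0.39), −0.04 (SE 0.38), −0.16 (SE 0.29) and −0.12 (SE 0.40), with adjusted p of 0.88 to 0.98. Nos3 had −0.53 (SE 0.33, adjusted p = 0.57), Pparg −0.04 (SE 0.28, adjusted p = 0.98) and Ccl2 0.05 (SE 0.72, adjusted p = 0.99).

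Camera called 11 lists for AngII+VAL against AngII, 8 up and 3 down; no member passed over all genes. The skeletal muscle list had 17 of 17 members higher (mean difference 3.90; adjusted p = 3.1e-37, correlation p = 0.0775; exact permutation p = 0.0079, adjusted p = 0.338), and 16 passed adjusted over the list alone. Oxidative phosphorylation had 36 of 40 higher (0.29; adjusted p = 1.3e-10, correlation p = 0.669), with Uqcrc1, of complex III, at 0.59 (SE 0.33, adjusted p = 0.53). Erythrocyte and platelet genes had 10 of 10 higher (0.79; adjusted p = 1.0e-07, correlation p = 0.374), 1 of them adjusted over the list alone, with the red cell membrane gene Slc4a1 at 0.91 (SE 0.29, adjusted p = 0.25). Brown adipocyte genes had 17 of 19 higher (0.42; adjusted p = 1.0e-05, correlation p = 0.581), with Fabp3 at 1.45 (SE 0.61, adjusted p = 0.38) and Plin5 at 0.90 (SE 0.38, adjusted p = 0.38). Fatty acid oxidation had 20 of 27 higher (0.27; adjusted p = 1.0e-05, correlation p = 0.581), with Pdk4 at 1.02 (SE 0.42, adjusted p = 0.37) and Ucp3 at 0.78 (SE 0.31, adjusted p = 0.36). The 23 neuron genes were all lower (−1.78; adjusted p = 2.4e-06, correlation p = 0.699), with Chga at −2.09 (SE 0.77, adjusted p = 0.31) and Hand2 at −1.83 (SE 0.68, adjusted p = 0.32), and a score of 3.96 in AngII+VAL 4. All 13 Schwann cell genes were lower (−0.83; adjusted p = 0.000237, correlation p = 0.501), 8 of them adjusted over the list alone. B cell genes had 8 of 10 higher (0.96; adjusted p = 0.00044, correlation p = 0.602), with scores of 4.91 in AngII+VAL 2 and 4.85 in AngII+VAL 5 and 1.74 to 2.92 in the others. T cell genes (0.32; adjusted p = 0.0117, correlation p = 0.713) lost their call without AngII+VAL 5 (adjusted p = 0.351), and fibroblast genes, all 17 lower (−0.50; adjusted p = 0.0117, correlation p = 0.713), lost it without AngII 3 (adjusted p = 0.114). With a term for kidney transcript level the direction of the T cell list turned too. With the neuron and muscle scores as terms the oxidative phosphorylation, fatty acid oxidation, brown adipocyte, mitochondrial, fibroblast and Schwann cell calls were lost (adjusted p = 0.232, 0.137, 0.283, 0.0747, 0.826 and 0.981), and the oxidative phosphorylation, fibroblast and Schwann cell directions turned. Mitochondrially encoded genes were higher (0.57; adjusted p = 0.0013, correlation p = 0.389; 1 adjusted over the list alone), but quantile normalization turned the list's direction and ended the call. In the other lists 0 members passed adjusted over the list alone, and the adjusted p of the 11 lists over all settings was 1.6e-40 to 0.981.

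Kidney transcripts were highest in AngII+VAL. Kap, an androgen-regulated kidney protein gene chosen after its values were seen, was at 65.6 to 92.1 FPKM in 6 libraries (AngII+VAL 1 to 5 and AngII+BAI 5), at 14.9 to 29.0 in 12 libraries and at 0 to 2.37 in the other 12. In the order of deposit the 2 lower levels alternated, with a change in 19 of 19 neighbouring pairs within groups. With a term for this level, 181 genes passed for AngII+VAL against AngII, 24 higher and 157 lower. That model separates level and drug through 1 library, AngII+BAI 5.

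**Figure D3:**
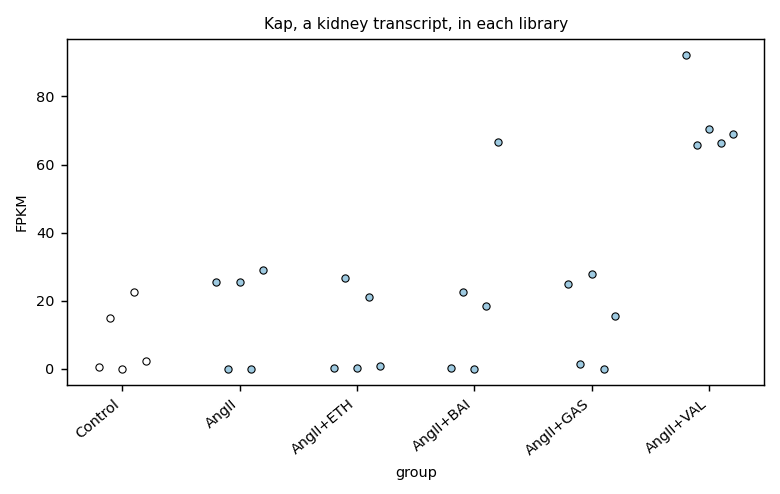
FPKM of the kidney gene Kap in each of the 30 libraries, by group; each point is a library. All 5 AngII+VAL libraries and AngII+BAI 5 were at 65.6 to 92.1 FPKM, the others at 29.0 or less.

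Each compound group was also set against Control, to ask what remained different from saline. With baicalin 190 genes differed from Control, 146 higher and 44 lower, against 96 and 81 after quantile normalization and 146 and 115 with TMM factors. Far fewer passed with array weights or in a model of the 2 groups alone. Ttc9 rose from 1.35 ± 0.757 to 8.87 ± 1.56 FPKM (2.12, SE 0.36, adjusted p = 0.0073) and Emp1, an epithelial membrane protein gene, from 12.2 ± 0.814 to 120 ± 70.8 (3.03, SE 0.67, adjusted p = 0.038). Limch1 (ENSMUSG00000037736, chromosome 5, 66745827 to 67057158, plus strand), an actin-binding protein gene, went from 51.6 ± 10.6 to 17.3 ± 9.94 FPKM (−1.67, SE 0.25, adjusted p = 0.0061), Ankrd46 from 18.9 ± 3.35 to 3.57 ± 0.968 (−2.13, SE 0.45, adjusted p = 0.029) and Tnrc18 from 11.5 ± 1.38 to 3.04 ± 4.01 (−2.25, SE 0.50, adjusted p = 0.037). Voom called 28 genes, 14 in each direction, and with a term for kidney level 10 passed, 9 of them among the 190. The count was 10, 11, 11 and 17 without Control 1, 2, 3 and 4, and 29, 954, 20, 651 and 8 without AngII+BAI 1, 2, 3, 4 and 5. With gastrodin 1 gene passed: Hspd1 (ENSMUSG00000025980, chromosome 1, 55077835 to 55088243, minus strand) fell from 104 ± 19.3 to 32.6 ± 4.34 FPKM (−1.63, SE 0.27, adjusted p = 0.024), while voom also called 1 and array weights 8. That count was 0 without Control 1, 2 or 4 and without each AngII+GAS library. With ethoxysanguinarine and valsartan 0 genes passed by limma or voom, with 685 and 508 at an unadjusted p under 0.05, while array weights called 8 and 24, unlisted transcripts set to 0 gave 9 and 21, and 1 gene passed in each without Control 5.

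The plant compounds were compared with valsartan, given at another dose. With baicalin 79 genes differed, 71 higher and 8 lower, against 74 and 23 after quantile normalization and 60 and 26 with TMM factors; voom called 0, array weights 2, and 2244 genes had an unadjusted p under 0.05. Higher with baicalin were Phf5a, a splicing factor gene (12.7 ± 2.58 against 1.81 ± 1.04 FPKM; 2.35, SE 0.48, adjusted p = 0.03), Rps6kb1, a kinase gene of the mTOR pathway (8.66 ± 3.42 against 1.67 ± 0.425; 1.76, SE 0.40, adjusted p = 0.036), and Tsc22d3, a glucocorticoid-induced gene (61.7 ± 26 against 20.8 ± 6.95; 1.5, SE 0.34, adjusted p = 0.039). Lower were Ankrd46 (3.57 ± 0.968 against 19.4 ± 2.01 FPKM; −2.18, SE 0.45, adjusted p = 0.03), the polycomb gene Cbx7 (2.57 ± 1.8 against 7.9 ± 1.67; −1.47, SE 0.35, adjusted p = 0.043) and Asb2 (10.6 ± 4.48 against 26.3 ± 5.19; −1.31, SE 0.29, adjusted p = 0.035). Rps6kb1 was also at 1.85 to 2.94 FPKM in AngII 5, AngII+ETH 2, 3 and 5, AngII+BAI 2 and AngII+GAS 1, and Ankrd46 at 3.39 to 4.31 in AngII 2 and 3 and AngII+GAS 4. With a term for kidney level 166 genes passed, 4 of them among the 79. The count was 10, 730, 1, 333 and 147 without AngII+BAI 1, 2, 3, 4 and 5, and 0, 3, 0, 0 and 37 without AngII+VAL 1, 2, 3, 4 and 5. For ethoxysanguinarine and gastrodin against valsartan limma and voom called 0 genes, with 580 and 700 at an unadjusted p under 0.05, while array weights called 4 and 30, unlisted transcripts set to 0 gave 20 and 24, and 1 gene passed for gastrodin without AngII+GAS 3.

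Reversal of the infusion's changes was measured by the correlation across genes of fold changes against AngII with those of AngII against Control. Both comparisons share the AngII libraries, which alone makes the correlation negative. All 5 AngII libraries in both gave −0.516 for ethoxysanguinarine, −0.454 for baicalin, −0.707 for gastrodin and −0.668 for valsartan, where 1000 simulations of unchanged groups gave −0.494 ± 0.122. With the AngII libraries split 3 and 2 in 10 ways, so that none was shared, the mean correlation was −0.036 ± 0.12 for ethoxysanguinarine and −0.11 ± 0.10 for baicalin. It was −0.25 ± 0.083 for gastrodin and −0.26 ± 0.075 for valsartan, where the simulation gave 0.0022 ± 0.112. A one-sided simulation p for the split covariance was 0.366 for ethoxysanguinarine, 0.122 for baicalin, 0.008 for gastrodin and 0.005 for valsartan, unadjusted over these 4. The two-sided simulation p was 0.731, 0.244, 0.016 and 0.01 in this order. The simulation pooled the spread within all 6 groups and did not carry the choice of transcripts by their AngII mean. That choice can itself shift the correlation, so these p-values do not settle whether a compound reversed the changes. Without AngII 5 the split correlations were 0.071, 0.017, −0.097 and −0.11 in this order, and without AngII 1 they were 0.022, −0.018, −0.14 and −0.16. Differences between compounds in this measure were not tested.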

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

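Tests chosen only after the result was seen are those of the order of deposit, of valsartan, of the baicalin libraries, of a rise of neuron transcripts in every aorta and of neuron scores at equal depth; the others were set beforehand. A library is given here where the gap to its nearest neighbour exceeded 0.71 of its group's range, which chance does in about 1 in 20 groups. Among library measures 7 of 42 groups held such a library (2.1 by chance), among list scores 15 of 162 (8.1) and among named genes 23 of 253 (12.65).

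Kidney transcripts stood at 3 levels, with mean Kap of 0.51 FPKM in 12 samples, 22.9 in 12 and 71.7 in 6. Valsartan was excluded as the whole cause, since among libraries without it the summed kidney genes other than Kap were at 0 to 0.281 FPKM at the low and 2.77 to 6.32 at the middle level, a difference of 2.38 (log2); a further rise with it stays open. Kidney tissue taken along freely at dissection was excluded for the 2 lower levels, which alternated in the order of deposit: all 19 neighbouring pairs within groups changed level (11.6 by chance; exact one-sided p = 3.3e-05, the smallest it can give). For the highest level such tissue and, for all levels, reads of kidney libraries carried over in batches stay open: 7 genes were called between the 2 lower levels at equal group (among them Kap, Slc34a1, Cltrn, Keg1, Miox and Klk1), with 431 at an unadjusted p under 0.05. Of 7 kidney genes not looked at before, 6 did not follow the levels (Fbp1 did), as bounded against carried-over reads, and the SD of their mean log2 level within the levels was 0.114 to 0.379 (0.263 to 0.315 for the 3 under 1 FPKM at the lowest level), as bounded against tissue (under 0.5), but neither decides, since 4 had means of 3.01 FPKM or more at the lowest level, which hides a small share, and 3 genes are fewer than the 5 needed, a need set after the values were seen.

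Baicalin libraries 3 and 5 had low contractile and high macrophage and cell cycle scores. Beyond the AngII range lay 2 of 5 baicalin libraries for macrophages (above) and contractile genes (below, at most 3 without any 1 AngII library). For the cell cycle 3 of 5 lay above it (1.08 to 2.09), but 5 of 5 without AngII 3. Neither library 3 nor 5 had the fewest reads or most transcripts at 0 (9.49% and 8.11%, against 10.5% to 21.5% in the other baicalin libraries). Lower quality stays open. Libraries 1, 3 and 5 had the lowest array weights (0.21, 0.259 and 0.321) and median correlations with other libraries (0.849, 0.833 and 0.852) of all 30. Without libraries 3 and 5 the median share kept of the 3 score differences was 0.0136 (macrophages −0.247, cell cycle 0.26), which a different tissue makeup of 2 aortas could give. The libraries were picked by these scores, so the counts above test no action of baicalin. An even or uneven action cannot be told apart from a different makeup.

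Neuron and Schwann cell transcripts were high in part of the AngII libraries. A rise by angiotensin II in every aorta stays open: 3 of 5 AngII libraries lay above the Control range of the neuron score (0.475 to 2.24), but 4 of 5 without Control 1 (range up to 0.619), where AngII 2 alone, at 0.527, lay within. Ganglion or nerve tissue taken along in part of the libraries may be a source: the median pairwise correlation of the 23 neuron genes within groups was 0.957, against at most 0.206 in 1000 random gene sets, and Gap43 reached 21.6 ± 26.2 FPKM in AngII. A difference in depth missed the bound set beforehand (Spearman under 0.2) with 0.206 over 30 libraries (permutation p = 0.272; Pearson 0.296, permutation p = 0.112), and was excluded by a later comparison: of the 6 other libraries outside Control with at least as many reads as AngII 1, 4 and 5 (78.2 M or more), 4 had scores within the Control range, and reads differed by at most 0.212 (log2) where scores differed by 5.1. A response of part of the animals to the infusion was not tested.

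Other libraries set apart are given with the range of the other 4 of their group. AngII 3 had 75.9 M reads (78.2 to 78.8). AngII+ETH 4 had 16.1% of FPKM in its top 10 genes (27.4 to 29.3) and 10.5% mitochondrial (19.1 to 21.3). Transcripts listed at 0 were 21.5% in AngII+BAI 1 (8.11 to 11.5) and 13.4% in AngII+GAS 2 (9.41 to 10.6). AngII+GAS 5 had a summed FPKM of 457000 (519000 to 535000) and 13.2% in assembled transcripts (10.9 to 11.3). The matrix score was 7.26 in AngII+BAI 5 (5.33 to 5.56), the inflammatory score 3.77 in AngII 3 (2.13 to 2.58), the T cell score 1.75 in AngII+ETH 5 (1 to 1.15) and 2.95 in AngII+VAL 5 (1.01 to 1.51), and the B cell score 1.65 in AngII 1 (2.41 to 2.66). In AngII+ETH 4 the brown adipocyte score was 3.79 (5 to 5.25), the mitochondrially encoded score 10.9 (11.5 to 11.6) and the fatty acid oxidation score 5.36 (5.96 to 6.08). The neuron score was 2.24 in Control 1 (0.475 to 0.619), 2.61 in AngII+GAS 2 (0.397 to 0.523) and 3.96 in AngII+VAL 4 (0.352 to 1.2). The erythrocyte score was 4.07 in AngII 2 (5.49 to 5.86), and the cell cycle score 1.65 in Control 5 (0.949 to 1.14), 2.09 in AngII 3 (1.08 to 1.36) and 0.925 in AngII+VAL 1 (1.4 to 1.47).

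Single genes (FPKM) set a library apart as follows. In AngII+ETH 4, Atp5d was 48.9 (82.7 to 88.5), Ucp1 475 (1840 to 2580) and mt-Co2 6670 (14900 to 16800), and in AngII+ETH 1 Nr1d1 was 20.2 (78 to 99.5) and Pex5l 2.14 (0.255 to 0.421). In Control 1, Plin5 was 20.6 (32.4 to 38.7), Mal 2.17 (0.925 to 1.21), Hand2 1.55 (0.216 to 0.498) and Gap43 2.97 (0.231 to 0.618). In AngII 3, Agap2 was 0 (1.04 to 1.47) and Ccna2 4.58 (0.767 to 1.35), and in AngII 5 Kit was 12.8 (5.39 to 6.22). Among baicalin libraries, Col1a1 was 2980 in AngII+BAI 5 (300 to 403), Rps6kb1 2.89 in AngII+BAI 2 (8.72 to 11.7) and Gucy1a1 8.5 in AngII+BAI 3 (18.7 to 21.9). Among gastrodin libraries, Chga was 1.67 (0 to 0.233) and Hand2 3.51 (0.174 to 0.418) in AngII+GAS 2, Sox10 1.13 in AngII+GAS 1 (0 in the others), Dag1 40.1 in AngII+GAS 3 (90.5 to 115) and mt-Co1 19200 in AngII+GAS 5 (40000 to 45200). In AngII+VAL 4, Chga was 1.58 (0 to 0.2), Hand2 9.16 (0.0899 to 0.608) and Nos3 2.33 (1.42 to 1.49).

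Annotated transcripts listed for a compound group and not for Control or AngII entered no comparison except with unlisted transcripts set to 0. With all 5 libraries at 0.5 FPKM or more there were 25 for AngII+ETH, 21 for AngII+BAI, 20 for AngII+GAS and 51 for AngII+VAL, of 1140, 2012, 1167 and 1119 listed so. Their levels in Control and AngII were not analysed here, where the AngII mean lay under 0.5 FPKM.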

How the results depend on the processing

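Settings chosen after the results were seen are named above. The others were planned. Of 158 named gene comparisons reported, the 27 past the threshold had ranges that did not overlap, mostly by the rule for naming. Their sign, largely fixed by this, was kept in every setting run. None passed in every setting (32% to 96% of the settings). Of the 131 not past it, 92 kept their sign and 39 turned in at least 1 setting, and 21 passed in some setting. Leaving out single libraries moved 0 of the 27 and 67 of the 131 by over 1.5 times. Of 3918 fold changes over all settings 108 had the sign turned, 49 of them with single libraries left out. Limma without trend and robust moved no count by over 1.5 times, and gave 50 genes for AngII+BAI against AngII. A smaller model or a left-out library has fewer samples, and a stricter filter fewer genes; otherwise the cause of a change was not tested. Depth limits low genes, as the floors above show. Values below are for settings that moved a count by over 1.5 times, changed the side of the threshold or turned a sign.

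With a pseudocount of 5, the gene count was 3 for AngII against Control, 7 for AngII+VAL against Control, 4 for AngII+ETH against AngII+VAL and 5 for AngII+GAS against AngII+VAL. Signs of log2 fold changes turned for Ccl2 (−0.083) for AngII+ETH against AngII and for Ccl2 (−0.094) for AngII+VAL against AngII. With no filter on low values, the gene count was 4 for AngII against Control. With array weights, the gene count was 64 for AngII against Control. Against AngII it was 0 for AngII+BAI and 232 for AngII+GAS. Against Control it was 8 for AngII+ETH and AngII+GAS, 25 for AngII+BAI and 24 for AngII+VAL. Against AngII+VAL it was 4 for AngII+ETH, 2 for AngII+BAI and 30 for AngII+GAS. Turned log2 fold changes were those of Acta2 (−0.069) for AngII+ETH against AngII and for Col3a1 (−0.032) for AngII+BAI against AngII. With transcripts in place of genes, the transcript count was 3 for AngII against Control, 1 for AngII+VAL against AngII, 64 for AngII+BAI against Control, 0 for AngII+GAS against Control and 1 for AngII+BAI against AngII+VAL. With AngII+BAI 3 and 5 left out, the gene count was 18 for AngII against Control, 102 for AngII+BAI against AngII and 47 for AngII+BAI against AngII+VAL. Against Control it was 1 for AngII+ETH, 33 for AngII+BAI and 2 for AngII+GAS and AngII+VAL. Log2 fold changes that turned were those of Acta2 (0.41), Col3a1 (−0.43), Nos3 (−0.34) and Ccl2 (−0.086) for AngII+BAI against AngII. With AngII+BAI 1, 3 and 5 left out, the gene count was 25 for AngII against Control, 9 for AngII+BAI against AngII and 7 for AngII+BAI against AngII+VAL. Against Control it was 1 for AngII+ETH, 12 for AngII+BAI and 4 for AngII+VAL. The log2 fold change turned for Acta2 (0.20), Mylk (0.088), Col3a1 (−0.67), Nos3 (−0.35), Ccl2 (−0.58) and Rps2 (−0.025) for AngII+BAI against AngII. With a filter at 5 FPKM, the gene count was 16 for AngII+BAI against AngII and 1 for AngII+GAS against AngII. With the model fitted to the 2 groups compared alone, the gene count against AngII was 0 for AngII+BAI and AngII+GAS and 19 for AngII+VAL. Against Control it was 5 for AngII+BAI and 3 for AngII+ETH, AngII+GAS and AngII+VAL. Against AngII+VAL it was 5 for AngII+ETH, 2 for AngII+BAI and 13 for AngII+GAS. With voom on the recovered reads, the gene count was 23 for AngII+BAI against AngII, 0 for AngII+GAS against AngII, 28 for AngII+BAI against Control and 0 for AngII+BAI against AngII+VAL. With unlisted transcripts set to 0, the gene count against AngII was 74 for AngII+BAI, 8 for AngII+GAS and 18 for AngII+VAL. Against Control it was 9 for AngII+ETH, 329 for AngII+BAI, 5 for AngII+GAS and 21 for AngII+VAL. Against AngII+VAL it was 20 for AngII+ETH, 172 for AngII+BAI and 24 for AngII+GAS. Signs of log2 fold changes turned for Agap2 (0.27) for AngII+ETH against AngII. With the neuron and skeletal muscle scores as terms, the gene count was 0 for AngII+BAI and AngII+GAS against AngII. Against Control it was 58 for AngII+BAI and 0 for AngII+GAS. Against AngII+VAL it was 1 for AngII+ETH and 41 for AngII+BAI. In that model 8 gene lists were called for AngII against Control. Turned log2 fold changes were those of Myh11 (−0.063), Mylk (−0.016), Myl9 (−0.012) and Pparg (0.023) for AngII against Control, Myh11 (0.067), Mylk (0.10) and Ccl2 (−0.22) for AngII+ETH against AngII, Col1a1 (0.27) for AngII+BAI against AngII, Agtr1a (0.037) and Nos3 (0.15) for AngII+GAS against AngII and for Ace (0.14), Myh11 (0.43), Mylk (0.32), Myl9 (0.54), Fn1 (0.86), Ccl2 (−0.96) and Fabp3 (−0.19) for AngII+VAL against AngII. With a pseudocount of 0.1, the gene count was 1 for AngII+GAS against AngII. With quantile normalization, the gene count was 0 for AngII+GAS against AngII, 6 for AngII+VAL against Control and 3 for AngII+GAS against AngII+VAL. Log2 fold changes that turned were those of Acta2 (0.30) and Myh11 (−0.055) for AngII against Control, Acta2 (−0.099), Mylk (0.031) and mt-Co2 (−0.11) for AngII+ETH against AngII, Mylk (0.077), Nos3 (0.16) and mt-Co1 (−0.12) for AngII+GAS against AngII and for Acta2 (−0.12) and Pparg (0.052) for AngII+VAL against AngII. With the kidney transcript level as a term, the gene count was 181 for AngII+VAL against AngII. Against Control it was 10 for AngII+BAI and 21 for AngII+VAL. Against AngII+VAL it was 47 for AngII+ETH, 166 for AngII+BAI and 35 for AngII+GAS. In that model 17 gene lists were called for AngII+VAL against AngII. The log2 fold change turned for Myh11 (−0.063) for AngII against Control, Myh11 (0.006) and Mylk (0.021) for AngII+ETH against AngII, Col3a1 (−0.24) for AngII+BAI against AngII and for Myh11 (0.91), Mylk (0.61), Myl9 (0.68), Pparg (0.40) and Ccl2 (−0.92) for AngII+VAL against AngII. With TMM factors, the gene count was 0 for AngII+GAS against Control. Signs of log2 fold changes turned for Myh11 (−0.12) for AngII against Control, Myh11 (0.026) and Mylk (0.059) for AngII+ETH against AngII, Mylk (0.12) and Nos3 (0.067) for AngII+GAS against AngII and for Myh11 (0.091), Myl9 (0.016) and Pparg (0.091) for AngII+VAL against AngII. With an estimated correlation the number of gene lists called was 0 in each of the 5 main comparisons. The correlation with the angiotensin II changes was −0.516 (AngII+ETH), −0.454, −0.707 and −0.668 with the AngII libraries not split, which lowers it by construction. Split, over genes at an unadjusted p under 0.05, it was 0.043 for AngII+ETH, −0.393 for AngII+GAS and −0.344 for AngII+VAL.

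Leaving out each library in turn gave gene counts of 0 to 41 for AngII against Control. Against AngII they were 0 to 184 for AngII+BAI and 0 to 61 for AngII+GAS. For AngII+BAI they were 8 to 954 against Control and 0 to 730 against AngII+VAL. Other counts that changed were 0 to 1. For AngII+ETH against AngII 6 to 17 gene lists were called. The split correlation of the reversal ran from −0.13 to 0.071 for AngII+ETH, −0.18 to 0.017 for AngII+BAI, −0.29 to −0.097 for AngII+GAS and −0.31 to −0.11 for AngII+VAL. Log2 fold changes of genes not past the threshold that turned were Acta2 (−0.13 to 0.082), Myh11 (−0.083 to 0.052), Pparg (−0.19 to 0.027) and Ccl2 (−0.21 to 0.64) for AngII against Control, Acta2 (−0.11 to 0.096), Myh11 (−0.21 to 0.04), Mylk (−0.18 to 0.082), Col1a1 (−0.57 to 0.029), Col3a1 (−0.57 to 0.082), Fn1 (−0.047 to 0.49), Pparg (−0.28 to 0.017) and Ccl2 (−0.23 to 0.61) for AngII+ETH against AngII, Col1a1 (−0.72 to 0.28) and Col3a1 (−0.23 to 0.78) for AngII+BAI against AngII, Acta2 (−0.50 to 0.019), Mylk (−0.24 to 0.076), Nos3 (−0.34 to 0.07), Pparg (−0.05 to 0.49) and Ccl2 (−0.69 to 0.16) for AngII+GAS against AngII, Myh11 (−0.12 to 0.019), Pparg (−0.12 to 0.075) and Ccl2 (−0.22 to 0.63) for AngII+VAL against AngII.

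In 100 splits of the 10 libraries of a comparison into 5 and 5, the real one included, at most 4 splits reached the real value for 6 gene counts. This excludes chance only without adjustment over the tests. For AngII against Control 1 split had as many genes at an unadjusted p under 0.05 as the real 1480 (highest other 1444), for AngII+VAL against AngII 1 as many as 1429 (1383) and for AngII+ETH against Control 2 as many as 685 (782). With no effect 661 such genes are expected. For genes past the threshold, 1 split reached the 190 of AngII+BAI against Control (3), 2 the 79 of AngII+BAI against AngII+VAL (401) and 4 the 2 of AngII+GAS against AngII (93). Chance could not be excluded for AngII+BAI against AngII (8 splits with 44 or more, highest other 927) and AngII+GAS against Control (12 with 1 or more, 2), nor for genes at an unadjusted p under 0.05 in AngII+ETH against AngII (41 with 451 or more, 1438), AngII+VAL against Control (6 with 508, 756), AngII+ETH against AngII+VAL (14 with 580, 1201) and AngII+GAS against AngII+VAL (16 with 700, 2140). The splits that called 927, 93 and 401 genes point to a structure of the samples other than the groups. For the number of gene lists, adjusted within the comparison, chance could not be excluded in any main comparison: 40 splits had as many as the 13 of AngII against Control (highest other 19), 89 as many as the 7 of AngII+ETH (20), 14 as many as the 18 of AngII+BAI (21), 37 as many as the 12 of AngII+GAS (20) and 57 as many as the 11 of AngII+VAL (21).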

Other observations

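The values in this part were picked after the results were seen, and no hypothesis was tested on them. Of the 36 gene lists tested with camera, 9 were called in none of the 5 main comparisons: TGF-beta targets, the renin-angiotensin-aldosterone system, vasoactive receptors, interferon response, neutrophils and mast cells, lymphatic vessels, the NRF2 antioxidant response, heat shock and histones. Single members passed limma's threshold over all genes in such lists with baicalin: Gstm1 in the NRF2 list, Kit in the mast cell list and Gucy1a1 in the vasoactive list.

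Transcripts listed with valsartan and not for Control or AngII included Umod, of kidney tubules (2.29 ± 0.352 FPKM).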
